A study of Mus musculus with 2 samples.

How the data were processed

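Total RNA of lung was sequenced in 2 mouse pups of strain B6NCrl on postnatal day 0, the day of birth. Each library was made from the 2 lungs of a single pup. Replicate 1 is pup 1 and replicate 2 is pup 3, and the labels give both the same pregnancy number, 1. The labels also give both libraries the same donor identifier, so that n = 2, each SD and each difference between the pups rest on the pup numbers alone. The sex of the pups was not collected, per the labels. RNA longer than 200 nt was extracted with the Ambion mirVana kit, 10 ng went into each library, and the labels name spike-in RNAs and a manual of the SMARTer low-input kit. Total RNA libraries can hold transcripts without a poly(A) tail, and the cDNA chemistry, the fragment size selection and the low input can each change which transcripts are seen.

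The gene and transcript tables hold expected counts, which are estimated counts that need not be whole numbers because reads shared by several features were split between them, per the file headers. The deposited TPM divides expected counts by the effective length of the feature and scales each library to the same total, and the deposited FPKM was scaled by length without that step. A deposited isoform percent gives the share of a gene's abundance held by each of its transcripts. Posterior mean counts, TPM and isoform percent stand beside these in the deposited tables and were used as alternatives. The assembly mm10 and the annotation M4 are named in the text files deposited with the libraries. The aligner and the counting program are not given in the sources used here, and neither is whether counting used strand. Antisense genes and genes that overlap others are therefore uncertain.

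The tables list 69691 features, of which 43346 are mouse genes, 26248 are named only by a number, 96 are ERCC spike-ins and 1 is phiX. Gene names, biotypes and coordinates came from GENCODE M21, a later annotation on the same assembly (GRCm38, also called mm10), matched by gene identifier without its version. It held 42462 of the 43346 gene identifiers. The 884 others carried 0.137% of the counts of pup 1 and 0.151% of those of pup 3. Expected counts over genes summed to 42189536 in pup 1 and 37026165 in pup 3. At these depths the limit that a count of 0 allows, 3 counts, equals 0.0711 CPM in pup 1 and 0.0810 CPM in pup 3. Effective length was within 0.5 of length minus 99 in all 26143 single-transcript genes, so the TPM of very short genes rests on few possible positions. Ratio intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

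There is 1 group, so the series implies no comparison between conditions. Levels are means ± SD over the 2 pups. Pairs of gene lists were compared within each library as the difference of their mean log2(TPM + 1), and the smallest 2-sided p that an exact sign-flip test can give with 2 pups is 0.5, so no such p is printed. The pups were also compared with each other. That comparison sets 1 library against 1 library, has no replicate check and carries no p-value. Expected counts were rounded and scaled by TMM (edgeR 4.0.16, R 4.3.3), which set the effective size of pup 1 at 1.11 times that of pup 3. A gene was said to differ when its ratio was at least 2-fold, it had at least 50 counts over both libraries and the exact conditional binomial 95% interval of its ratio left out 1. Log2 ratios of counts, and with them the 2-fold rule, carry a prior count of 0.5. Folds printed with a 95% interval or against the floor are ratios of scaled counts without it. A gene list's median log2 ratio was placed among 10000 random lists of the same size, matched gene by gene to the 200 nearest genes by summed count. That percentile describes these libraries and is not a test between conditions.

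Before the data were examined, 57 gene lists, 13 pairs of lists and 18 genes for isoform shares were fixed, along with the alternatives and the rule for naming genes. That rule takes the 20 genes with the highest mean TPM outside the mitochondrial genome, the spike-ins and ribosomal RNA. From each list of interest it takes the 3 members with the highest mean TPM and any member under TPM 1 in both pups, and from the genes that differ the 10 largest ratios in each direction. The isoform genes are named as well. Not every gene that the rule takes is reported here. Of the list members, 2 had no match (Ahsp and Snhg1). A further 8 lists were added after the data were seen and are used only in the closing section.

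The fold and interval parts of the size rule and the list percentile were tested on simulated data with the fitted dispersion (common dispersion 0.0132, a coefficient of variation of 11.5%, from 15790 genes with 1 residual degree of freedom). The genes were chosen for at least 50 counts before the simulation, and the count threshold was not applied again to the simulated counts, so that threshold was not tested. Of 15790 simulated genes, 100 changed by 3-fold and 100 by 8-fold. The rule recovered 100% of each, all in the right direction, and called 26 unchanged genes. Of 100 lists of unchanged genes, 2 fell outside the central 95% of matched lists. The simulated genes varied independently and had no trend with length, so lists of genes that vary together were not tested. They also shared 1 dispersion at every depth. In the data the central 68% of log2 ratios spanned ± 0.45 at 50 to 200 counts and ± 0.16 at 5000 or more. The 26 calls therefore do not give the number of false calls in the data, and low-count genes could have more.

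Alternatives changed the TPM threshold, the pseudocount, the unit (posterior mean TPM, FPKM, CPM), the scaling (total counts, DESeq2 1.42.0 size factors, spike-in counts), the fold and count thresholds, filters on low values, and left out each pup in turn. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used, with blastn 2.17.0 for sequence matches. Features named only by a number, spike-ins and phiX were left out of gene counts and scaling, apart from the spike-in alternative.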

Results

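Lung RNA from 2 newborn mice was profiled to describe the transcriptome of the organ at birth. The 2 libraries form a single group, held 42189536 (pup 1) and 37026165 (pup 3) expected counts over genes, and allow levels within the tissue and differences between the pups to be described, but no comparison between conditions. All values below are given per pup or as mean ± SD (n = 2), in TPM unless another unit is named. Coordinates are on mm10 from GENCODE M21.

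Surfactant, globin and secretoglobin transcripts dominated the lung. Sftpc (chromosome 14, 70520949 to 70524081), which encodes surfactant protein C, stood at 73149 ± 5895 TPM, or 7.31% of all TPM. Hba-a2, an adult alpha globin, reached 27127 ± 3526 TPM, Scgb1a1 (chromosome 19, 9083636 to 9087958), the club cell secretoglobin, 23211 ± 228 TPM, and Hbb-bs, an adult beta globin, 15827 ± 2049 TPM. Hba-a1 followed at 10914 ± 1519 and Hbb-bt at 7043 ± 675 TPM. Actb stood at 7682 ± 76.9, Tmsb4x at 6888 ± 266, Scgb3a2 at 5634 ± 865, Ftl1 at 5231 ± 117, Sftpa1 at 4256 ± 67.0, Cbr2 at 4049 ± 15.7 and Fth1 at 3547 ± 8.89 TPM. The 20 highest genes by the rule held 25.2% of TPM in pup 1 and 25.4% in pup 3.

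Noncoding RNAs made up part of the same 20. Rn7s1 and Rn7s2, copies of the 7SL RNA of the signal recognition particle, were listed at 14999 ± 1095 and 14998 ± 1093 TPM. Near-identical copies share reads, so the level of each is uncertain. Malat1, a nuclear long noncoding RNA, stood at 7329 ± 863 TPM and Gm42418, a lincRNA by annotation only, at 5025 ± 448 TPM. Whether the reads of Gm42418 (263182 and 254041 counts in pups 1 and 3) are ribosomal RNA was not tested. The Malat1 value rests on an effective length of 429.55 bases, as 99.3% of it was assigned to Malat1-203, a model of 485 bases. The gene spans 5795690 to 5802672 on chromosome 19, so its TPM and rank would be lower on a longer transcript. Gm28437 (6988 ± 337 TPM) and Gm29216 (4350 ± 48.6 TPM) are pseudogenes on chromosome 1 whose sequences are 100% and 99.8% identical to mt-Co3 and mt-Co1 over 783 and 483 aligned bases, so reads of the mitochondrial genes can fall to them. Gm22133, annotated as a microRNA gene, was listed at 4393 ± 354 TPM on 1498 and 1137 counts, because its effective length was 10 bases. It lies within the span of Ftl1 (chromosome 7, 45457944 to 45459884), so its counts could be reads of Ftl1.

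In all, 14343 of 43346 genes reached TPM 1 in both pups, and 12929 of them were protein-coding, out of 21461 protein-coding genes in the tables. The detected genes included 191 lincRNA, 276 antisense and 377 processed pseudogene models, and antisense and pseudogene models can take reads from their partners. Levels of at least 100 TPM in both pups were found for 1396 genes and of at least 1000 TPM for 91. Protein-coding genes held 94.0 ± 0.112% of expected counts and genes of the mitochondrial genome 2.02 ± 0.0830%. Annotated ribosomal RNA genes held 2.00e-05 ± 5.26e-06% of counts, and ERCC spike-ins 0.000802 ± 7.22e-05%, which is 317 and 316 counts. The ribosomal share covers only the 353 features of that biotype outside the mitochondrial genome. Ribosomal reads given to other features are not in it, so it does not measure the ribosomal RNA content of the libraries.

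Markers of the alveolar epithelium were all detected. The 12 alveolar type 2 markers summed to 82853 ± 6136 TPM, led by Sftpc, Sftpa1 and Sftpd (1340 ± 111 TPM). The 12 alveolar type 1 markers summed to 5658 ± 296 TPM, led by Ager at 3453 ± 177, Emp2 at 537 ± 36.3 and Gprc5a at 533 ± 1.75 TPM. Ager (chromosome 17, 34597862 to 34600936) encodes the receptor for advanced glycation end products, a surface protein of type 1 cells. The type 2 list lay above the type 1 list by 1.96 ± 0.10 on the log2 scale of mean log2(TPM + 1), or 3.89-fold. A single gene sets much of the summed difference, since the ratio of summed TPM was 14.6-fold.

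The airway epithelium showed a steep order. Secretory cell markers, with 7 of 8 detected in both pups, summed to 29691 ± 1197 TPM, led by Scgb1a1, Scgb3a2 and Cyp2f2 (550 ± 51.1 TPM). Muc5b, a mucin, stood at 0.70 and 1.29 TPM. Ciliated cell markers, with 9 of 10 detected, summed to 928 ± 3.77 TPM and were led by Tppp3 at 607 ± 10.6, Dynlrb2 at 127 ± 2.72 and Tmem212 at 50.8 ± 2.62 TPM. Neuroendocrine markers summed to 27.1 ± 3.57 TPM, led by Ddc (13.3 ± 3.28), Calca (8.34 ± 0.742) and Scg5 (1.60 ± 0.226 TPM), while Chga and Chgb were under TPM 1 in both pups. The basal cell list had Krt15 at 24.8 and 52.0 TPM and Aqp3 at 7.60 and 13.5 TPM, then Krt14 at 2.04 and 1.56. Krt5, Trp63 and Ngfr, further markers of basal cells, were under TPM 1 in both. On the log2 scale type 2 markers exceeded secretory markers by 2.53 ± 0.13, secretory exceeded ciliated by 1.84 ± 0.03 and ciliated exceeded neuroendocrine by 3.48 ± 0.09.

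Endothelial markers were present for every vessel type on the lists. The 11 general endothelial markers summed to 2822 ± 75.8 TPM, led by Ramp2 (711 ± 44.0), Egfl7 (390 ± 36.0) and Cldn5 (368 ± 20.9). Lymphatic markers lay 3.69 ± 0.01 below them on the log2 scale, and Lyve1 at 244 ± 79.3 and Ccl21a at 144 ± 31.4 TPM led that list. The general capillary list, with Plvap at 223 ± 11.6, Gpihbp1 at 182 ± 47.4 and Aplnr at 76.6 ± 4.18 TPM, lay 0.64 ± 0.09 above the aerocyte list, which holds markers of the gas-exchange capillary cell such as Car4 (161 ± 11.6), Ednrb (95.5 ± 12.6) and Fibin (65.9 ± 1.71 TPM). The arterial list, led by Sox17 (82.9 ± 2.16), Cxcl12 (80.0 ± 4.40) and Gja4 (50.8 ± 0.658 TPM), exceeded the venous list, led by Nr2f2 (47.6 ± 6.91), Vwf (42.9 ± 8.36) and Vegfc (24.6 ± 1.32 TPM), by 0.41 ± 0.11. That order rests on Slc6a2, the venous member under TPM 1 in both pups, since leaving such members out gave -0.71.

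Fibroblast and mural markers had intermediate levels. The alveolar fibroblast list (all 9 members detected) summed to 1772 ± 62.9 TPM, led by Tcf21 at 648 ± 32.6, Limch1 at 294 ± 15.5 and Npnt at 285 ± 32.6 TPM. It lay 2.00 ± 0.09 above the myofibroblast list and 1.02 ± 0.00284 above the adventitial list on the log2 scale. Tgfbi (367 ± 9.32), Aspn (94.3 ± 8.62) and Hhip (52.4 ± 2.08 TPM) led the myofibroblast list, and Dach2 was under TPM 1 in both pups. Gsn (864 ± 29.0), Dpep1 (88.2 ± 3.92) and Dpt (81.2 ± 8.80 TPM) led the adventitial list. The smooth muscle and pericyte lists differed by -0.08 ± 0.02, with smooth muscle lower, and the ratio of summed TPM turned that order to 0.18. Acta2 (270 ± 24.2), Tagln (120 ± 12.8) and Actg2 (101 ± 7.91 TPM) led smooth muscle, and Cox4i2 (191 ± 14.3), Higd1b (110 ± 16.7) and Gucy1a1 (91.8 ± 3.79 TPM) led pericytes. Mesothelial markers were led by Msln, a surface protein of the pleural lining, at 457 ± 30.9 TPM.

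Matrix genes were among the higher mesenchymal transcripts. Mfap4 (1960 ± 90.5 TPM), Eln (1423 ± 78.3 TPM), which encodes elastin, and Mfap2 (362 ± 13.2 TPM) led the elastic fibre list. Col3a1 (555 ± 17.3), Col1a1 (416 ± 7.69) and Col6a1 (322 ± 26.0 TPM) led the collagen list, which holds genes of the fibrillar types I, III and V and of type VI, which forms beaded filaments. By mean log2(TPM + 1) the collagen list lay 0.62 ± 0.03 above the elastic fibre list, and by summed TPM the order turned to -1.12, where Mfap4 and Eln hold most of the elastic fibre sum.

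Myeloid and red cell transcripts exceeded those of lymphocytes. Macrophage markers summed to 3152 ± 406 TPM, of which Lyz2 held 2948 ± 401 TPM. Lyz2 has a close paralog, Lyz1, and alveolar type 2 cells express it too. C1qb stood at 44.8 ± 5.11 and Cd68 at 38.3 ± 0.940 TPM. Neutrophil markers included S100a8 at 380 ± 1.26, S100a9 at 186 ± 5.23 and Retnlg at 39.7 ± 6.09 TPM, with Elane and Mpo under TPM 1 in both pups. The macrophage list lay 0.91 ± 0.02 above the neutrophil list on the log2 scale, and that gap fell to 0.09 when members under TPM 1 in both pups were left out. The T and NK cell list summed to 10.2 ± 2.16 TPM, with Cd3e, Cd3d, Cd3g, Cd4, Cd8a, Il7r, Ncr1 and Klrb1c under TPM 1 in both pups. B cell markers summed to 22.1 ± 3.07 TPM, and Pax5 was under TPM 1 in both.

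Adult globins held 6.09 ± 0.777% of TPM. The embryonic globins stood far lower, with Hbb-y at 9.76 ± 0.311, Hba-x at 4.38 and 6.82 TPM in pups 1 and 3 and Hbb-bh1 at 0.19 ± 0.0707 TPM. The adult list exceeded the embryonic list by 11.59 ± 0.07 on the log2 scale. Xist, the RNA of the inactive X chromosome, stood at 19.3 and 22.8 TPM, and Ddx3y, Eif2s3y, Kdm5d and Uty on the Y chromosome had 0 counts in both libraries, where the floor is 3 counts.

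Markers of neighbouring tissue were low apart from cardiac muscle. Cardiac markers summed to 797 ± 79.8 TPM, led by Myl7 at 323 ± 49.7, Actc1 at 160 ± 14.3 and Tnnt2 at 87.9 ± 19.3 TPM, with Ryr2 under TPM 1 in both pups. Skeletal muscle markers summed to 51.6 ± 3.05, liver markers to 12.3 ± 4.43, markers of stratified epithelium to 7.58 ± 1.49 and thymus markers to 0.390 ± 0.0283 TPM. Cartilage markers summed to 9.92 and 8.93 TPM, of which Hapln1 held 6.98 and 6.17 TPM, and the nerve and glia list had no member at TPM 1 in both pups.

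**Figure D1:**
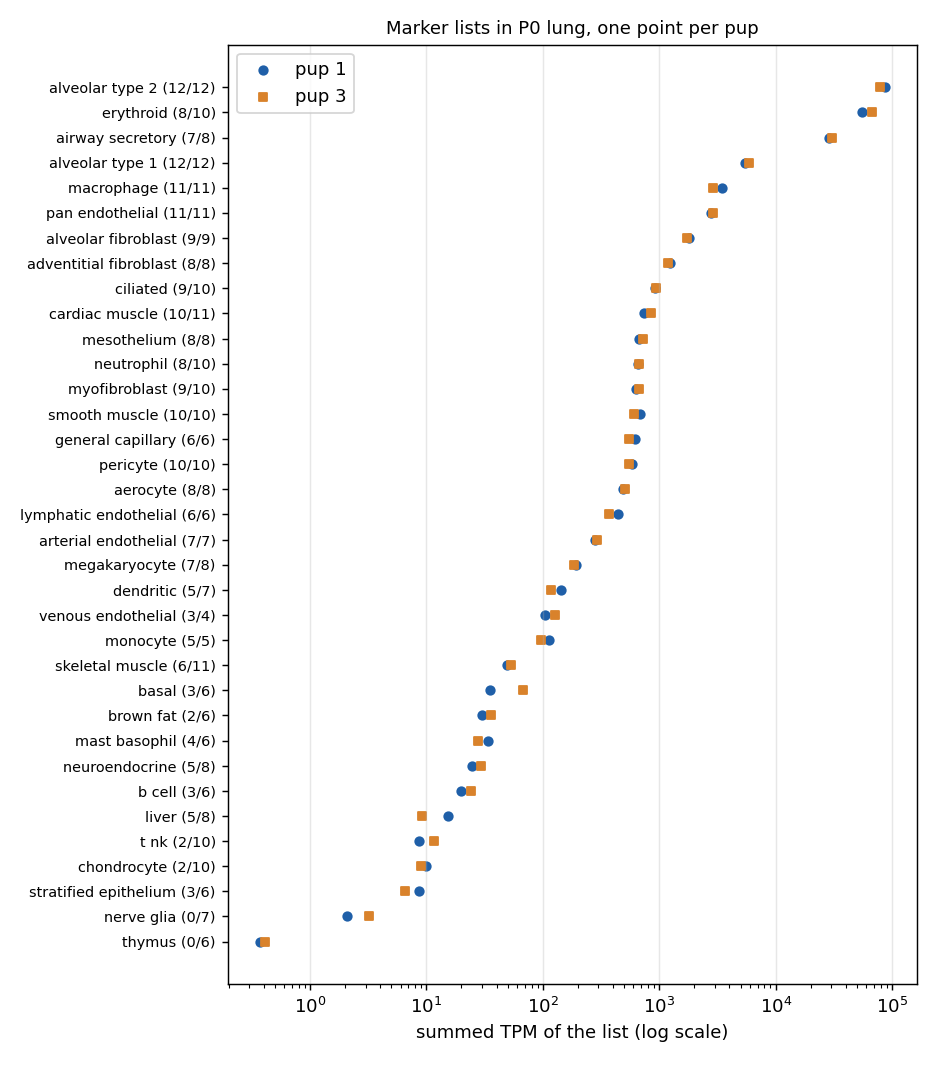
Summed TPM (horizontal axis, log scale) of each marker list in pup 1 (circles) and pup 3 (squares), with the number of members at TPM 1 or more in both pups out of all members in brackets. Alveolar type 2, red cell and secretory lists stand highest, at means of 82853, 61074 and 29691 TPM, and the thymus list stands lowest, at 0.390 TPM.

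Genes of other lung programs had the following levels. Id2 (388 ± 23.2), Foxf1 (155 ± 24.4) and Foxp1 (102 ± 4.46 TPM) led the list of lung transcription factors, all 19 of which were detected, and Nkx2-1 stood at 58.0 ± 3.56 TPM. Among growth factor ligands Pdgfa (97.1 ± 4.09), Wnt2 (55.0 ± 0.643) and Tgfb2 (47.3 ± 5.26 TPM) were highest. Aqp1 (540 ± 121), Aqp5 (425 ± 27.1) and Atp1b1 (354 ± 51.7 TPM) led the list of fluid transport genes. Fabp5 (502 ± 95.3), Elovl1 (311 ± 4.09) and Chpt1 (107 ± 3.07 TPM) led the surfactant lipid list. Among imprinted genes Meg3 (459 ± 63.6), Mest (406 and 432 TPM in pups 1 and 3) and Dlk1 (240 ± 118 TPM) were highest, and Peg10 was under TPM 1 in both pups. All 17 proliferation genes were detected, from 2.73 ± 0.884 TPM for Mki67 to 66.5 ± 1.22 TPM for Pcna.

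Isoform shares were alike in the pups for most of the 18 genes fixed for this purpose. In 17 of them the same transcript led in both pups, and in 13 the leading transcript held over 50% of the gene's abundance as a mean of the pups. In either pup alone it did so in 12, since Vegfa-211 held less in pup 1 and Tnc-204 in pup 3 (48.7%). Ager-201 held 73.9 ± 0.0141% of Ager, Pkm-201 94.8 ± 0.0424% of Pkm and Cd44-207 64.4 ± 0.148% of Cd44. Sftpc-201 and Eln-201 are the only transcripts of their genes in the tables. Sftpb-202, a model annotated as a target of nonsense-mediated decay, held 62.9 ± 0.672% of Sftpb, against 25.4 ± 0.156% for the protein-coding Sftpb-204. Fn1-202, a retained-intron model, held 60.4 ± 0.771% of Fn1. Vegfa was less even, as Vegfa-211 held 43.1% in pup 1 and 58.7% in pup 3 and Vegfa-201 held 41.3% and 24.4%. The leading transcript of H19 was H19-203 in pup 1 (36.9%) and H19-205 in pup 3 (36.5%). Col13a1-204 held 63.5 ± 4.88% of Col13a1, Igf1-202 66.5 ± 4.94% of Igf1, Enah-211 59.3 ± 1.07% of Enah, Tnc-204 50.1 ± 1.91% of Tnc and Malat1-203 99.3 ± 0.0141% of Malat1. Shares of Meg3-205 (44.9 ± 1.02%), Fgfr2-217 (38.4 ± 0.750%), Tpm1-211 (38.1 ± 0.219%) and Pdgfa-202 (35.5 ± 0.134%) were under 50%. These shares are model estimates that depend on which transcripts the annotation lists.

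Gene levels of the pups were close to each other. Across the 14343 detected genes log2(TPM + 1) had a Pearson r of 0.993 and a Spearman rho of 0.991, where genes are not independent replicates. The SD of the log2 ratio was 0.23. Among the 3501 genes with at least 5000 counts over both libraries the central 68% of log2 ratios spanned ± 0.16, against 0.03 from counting error, so the libraries are not the same reads counted again. Whether the spread comes from the pups or from library preparation was not tested.

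**Figure D2:**
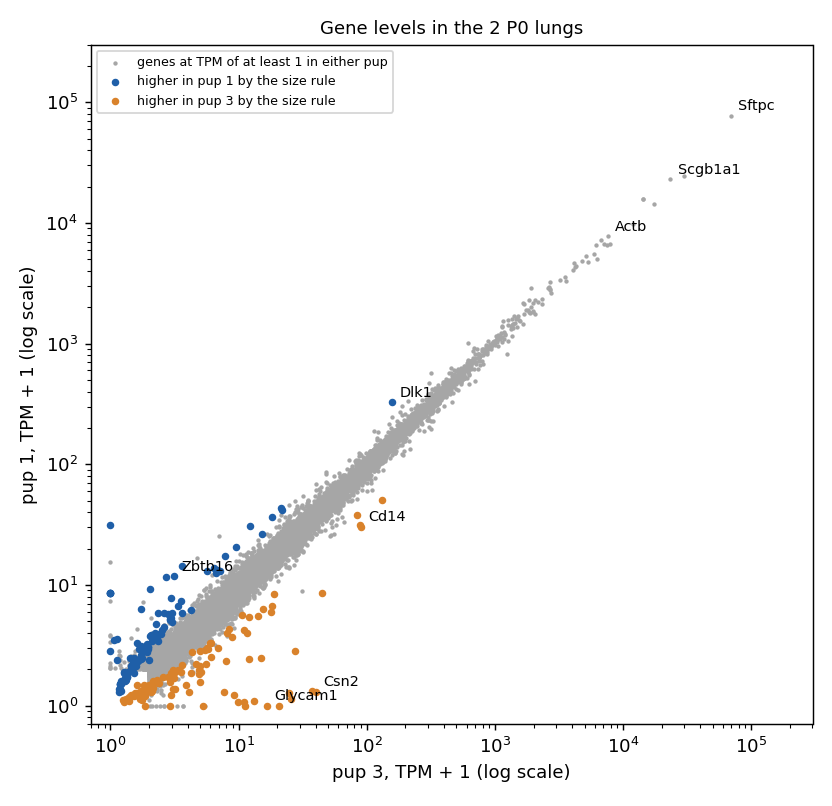
TPM + 1 of pup 1 (vertical axis, log scale) against pup 3 (horizontal axis, log scale) for genes at TPM 1 or more in either pup in grey, with the 104 genes higher in pup 1 and the 117 higher in pup 3 by the size rule in colour. Most genes lie near the diagonal, and Csn2 (0.30 and 39.3 TPM in pups 1 and 3) lies far from it.

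Milk protein genes and a chemokine were far higher in pup 3. Csn2 (chromosome 5, 87692624 to 87699630), which encodes beta casein, had 10 counts in pup 1 and 1102 in pup 3, and Csn1s1, an alpha casein gene, had 3 and 319 (118-fold, 95% interval 40 to 574). Wap (chromosome 11, 6635482 to 6638637), the whey acidic protein gene, had 2 and 303 counts (168-fold, 46.1 to 1392). Glycam1 had 0 and 225 counts, 83.1-fold higher in pup 3 against the floor of 3 counts (95% interval from 67.0). Lao1 had 0 and 54, 19.9-fold against the floor (95% interval from 15.7). With deposited TPM + 1 Lao1 (0 and 0.87 TPM) gave -0.90, but no gene under TPM 1 in both pups can reach 2-fold on that measure. Ccl20 (chromosome 1, 83116766 to 83119167), a chemokine gene, had 7 and 708 counts (112-fold, 54.1 to 280). Gm10233, Rpl30-ps9 and Gm15432 are pseudogenes at 0 counts in pup 1 and 92, 69 and 52 in pup 3. A gene identifier without a match in the later annotation, ENSMUSG00000103565.1, completes the 10 with 0 and 116 counts.

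Pseudogenes filled most of the largest ratios toward pup 1. Gm4294 had 504 and 0 counts in pups 1 and 3, at least 152-fold, and Gm15725 58 and 0. Rpl35a-ps2, Rpl35a-ps3, Rpl35a-ps4 and Rpl35a-ps6 had 57 and 0 counts each, equal values as an even division of shared reads would give, so each is uncertain. Gm10243, another processed pseudogene, had the same 57 counts in pup 1 but 280 in pup 3, and passed the size rule toward pup 3. Opposite ratios of this kind would arise if shared reads were divided differently in each library. They are therefore not read as differences between the pups, and the sequences of these copies were not compared. Zfp781 had 51 and 1 counts (46.0-fold, 7.90 to 1853), the antisense model Gm38287 161 and 6, the pseudogene Gm2274 223 and 10 and Cacng1, a calcium channel subunit gene, 51 and 4 (11.5-fold, 4.23 to 43.8). Ratios of pseudogenes are uncertain because they share reads with their parent genes.

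In total 221 of 15790 tested genes (1.40%) differed by the size rule, 104 higher in pup 1 and 117 higher in pup 3. Pseudogenes and unnamed gene models were 72 of the 221. Of named protein-coding genes, 65 were higher in pup 1 and 81 in pup 3. Scaling by spike-in counts moved the split to 161 higher in pup 1 and 82 higher in pup 3, since under it the log2 size of pup 1 over pup 3 fell by 0.14 against TMM and every log2 ratio rose by the same amount. The spike-in ratio of pup 1 to pup 3, 1.00, has a 95% interval of 0.856 to 1.18, which holds the TMM ratio of 1.11. Deposited TPM + 1 gave 31 and 54 genes.

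Glucocorticoid-responsive genes shifted toward pup 1. The list had a median log2 ratio of 0.43 (pup 1 over pup 3), at percentile 100 of 10000 matched random lists, and 7 of its 10 members were higher in pup 1. Zbtb16 (1746 and 293 counts, log2 ratio 2.42) and Per1 (2951 and 1275, 1.06) passed the size rule, but Per1 did not with deposited TPM + 1 (25.6 and 14.3 TPM, 0.80). Tsc22d3 at 334 and 209 TPM and Fkbp5 at 22.5 and 13.2 TPM did not, and Sgk1 was higher in pup 3, at 76.4 and 115 TPM. The median of these 10 genes lies midway between Klf9 (0.76) and Cebpd (0.11), so leaving out Zbtb16, Per1, Fkbp5, Tsc22d3 or Klf9 gave 0.11, at percentiles of 85.0 to 86.8, and leaving out any other member gave 0.76, at percentile 100. The mean of the list was 0.52.

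Cell cycle and ligand genes shifted toward pup 3. The proliferation list had a median log2 ratio of -0.24, with 12 of 17 members higher in pup 3, such as Birc5 at 13.2 and 23.2 TPM. The growth factor list had a median of -0.20 with 14 of 20 members higher in pup 3, such as Vegfa at 18.8 and 28.6 TPM. With TMM scaling all 4 adult globin genes were higher in pup 3 (median -0.18), and the cardiac list had a median of -0.23 with 9 of 11 members higher in pup 3. Spike-in scaling brought the medians to -0.09 for proliferation, -0.06 for growth factors, -0.04 for adult globins, where Hbb-bt (-0.11 with TMM) was no longer higher in pup 3, and -0.09 for cardiac genes. Scd1, which encodes a fatty acid desaturase and is in the surfactant lipid list, passed the size rule with 36.6 and 82.2 TPM (log2 ratio -1.08), but not with spike-in scaling (-0.94).

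Further lists shifted toward pup 1. The median log2 ratio was 0.30 for interferon-responsive genes, 0.25 for fluid transport (Aqp1 625 and 455 TPM), 0.16 for ribosomal proteins (83 of 88 members higher in pup 1) and 0.16 for imprinted genes, of which Dlk1 (324 and 157 TPM) passed the size rule. Ribosomal protein genes are short, and across 9725 genes with at least 1000 counts the log2 ratio fell with transcript length (Spearman rho -0.37), with a median of 0.12 in the shortest length class and -0.07 in the longest. The dendritic cell list had a median of 0.40 (Cd74 104 and 82.0 TPM), liver markers 0.51, mast cell and basophil markers 0.36 and stratified epithelium 0.47, where Alb, Tpsb2 and Ivl stood at 2.32, 11.7 and 2.45 TPM. The red cell list (-0.15), the venous list (-0.24), B cell markers (-0.46) and basal markers (-0.44) shifted toward pup 3. Spike-in scaling brought the medians to -0.00252 for the red cell list, -0.10 for the venous list, 0.40 for fluid transport, 0.31 for ribosomal proteins and 0.30 for imprinted genes. With the mean in place of the median, the fluid transport, dendritic, liver, mast cell, stratified epithelium, cardiac, venous, B cell, basal and red cell lists no longer fell outside the central 95% of matched lists, the last with a mean of 0.0134, and the alveolar type 1 (-0.07), secretory (-0.17) and cartilage (0.64) lists newly did. Without members under 10 counts the stratified epithelium list (percentile 97.4) and the basal list (-0.15, percentile 19.3) did not either, and the mitochondrial list, reduced to 15 members, did (0.17, percentile 99.4).

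Birc5, Vegfa, Fkbp5, Sgk1, Klf9, Alb, Tpsb2, Ivl and Cd74 were chosen as examples after values were seen. In total 17 of 57 lists fell outside the central 95% of matched lists, 9 above and 8 below, where 2.85 would if genes varied independently. Genes of a list can vary together, and lists were matched on summed count but not on length. More than 2.85 lists can therefore fall outside from library variation alone. Some lists share members, such as the red cell and globin lists. With all members kept, medians of the mitochondrial and sex-linked lists are set by members with 0 counts in both pups and are not read.

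**Figure D3:**
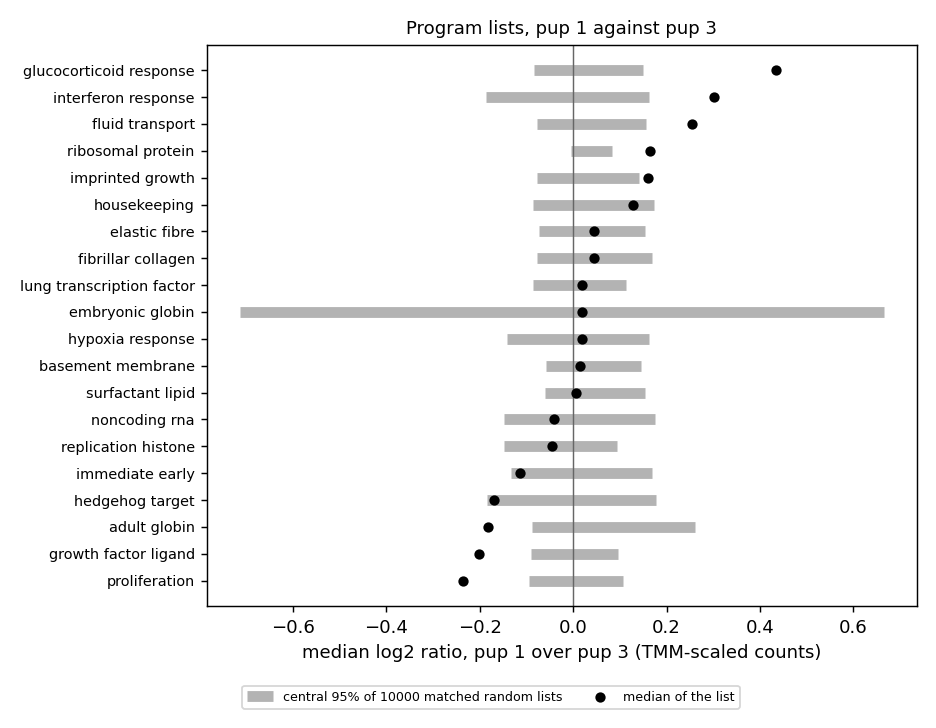
Median log2 ratio of pup 1 over pup 3 (horizontal axis) of each program list (points), with the central 95% of 10000 random lists of the same size matched on summed count (grey bars). The glucocorticoid list, at 0.43, lies farthest to the right and the proliferation list, at -0.24, farthest to the left.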

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

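No test in this part was chosen after the result was seen. Features named only by a number were set aside as outside the gene annotation, and they held 32 expected counts in pup 1 and 45 in pup 3, above the limit of 3 counts that a value of 0 allows. Feature 11364 held 30 and 35 of these, and what its sequence is was not tested. Gene identifiers that GENCODE M21 does not hold carried 0.137% of counts in pup 1 and 0.151% in pup 3. They remained in the counts and scaling, and no name or biotype was given to them. No biological explanation was tested for either, since the series has 1 group.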

How the results depend on the processing

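The alternatives were fixed in the plan, apart from leaving out each member of the glucocorticoid list and counting only genes of effective length of at least 200, which were chosen after the result was seen. No paired analysis was possible because there is one group.

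Differences between lists are log2 values. With summed TPM in place of the mean log2 they were 3.87 for type 2 minus type 1, 1.48 for type 2 minus secretory, 4.999 for secretory minus ciliated, 5.10 for ciliated minus neuroendocrine, 0.24 for capillary minus aerocyte, 2.80 for endothelial minus lymphatic, 1.32 for arterial minus venous, 1.44 for alveolar fibroblast minus myofibroblast, 0.55 for alveolar minus adventitial fibroblast, 0.18 for smooth muscle minus pericyte, 2.25 for macrophage minus neutrophil, 11.94 for adult minus embryonic globin and -1.12 for collagen minus elastic fibre. A pseudocount of 0.1 gave 2.70 for type 2 minus secretory, 1.79 for secretory minus ciliated, 4.24 for ciliated minus neuroendocrine, 3.96 for endothelial minus lymphatic, 0.54 for arterial minus venous, 2.17 for alveolar fibroblast minus myofibroblast, 1.07 for alveolar minus adventitial fibroblast, -0.11 for smooth muscle minus pericyte, 1.24 for macrophage minus neutrophil and 12.39 for adult minus embryonic globin. Leaving out the highest member of each list gave 1.74 for type 2 minus type 1, 3.01 for type 2 minus secretory, 1.22 for secretory minus ciliated, 3.34 for ciliated minus neuroendocrine, 4.29 for endothelial minus lymphatic, 0.59 for arterial minus venous, 2.09 for alveolar fibroblast minus myofibroblast, 1.27 for alveolar minus adventitial fibroblast, -0.14 for smooth muscle minus pericyte, 0.76 for macrophage minus neutrophil, 11.90 for adult minus embryonic globin and 0.79 for collagen minus elastic fibre. Without members under TPM 1 in both pups the values were 2.83 for ciliated minus neuroendocrine, -0.71 for arterial minus venous, 1.53 for alveolar fibroblast minus myofibroblast, 0.0870 for macrophage minus neutrophil and 10.65 for adult minus embryonic globin. In CPM, which is not scaled by length, the values were 1.75 for type 2 minus type 1, 3.32 for type 2 minus secretory, 3.32 for ciliated minus neuroendocrine, 0.30 for capillary minus aerocyte, 3.15 for endothelial minus lymphatic, 0.22 for arterial minus venous, 1.74 for alveolar fibroblast minus myofibroblast, 1.24 for alveolar minus adventitial fibroblast, -0.33 for smooth muscle minus pericyte, 1.67 for macrophage minus neutrophil, 10.87 for adult minus embryonic globin and 1.32 for collagen minus elastic fibre. Posterior mean TPM gave 3.36 for ciliated minus neuroendocrine, 3.65 for endothelial minus lymphatic and 0.87 for macrophage minus neutrophil. The order of the lists turned for smooth muscle and pericytes, arterial and venous, and collagen and elastic fibre. For arterial and venous the turn comes from leaving out Slc6a2, and the cause of the other changes was not tested.

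Leaving out each pup in turn gave log2 differences of 1.89 to 2.03 for type 2 minus type 1, 2.44 to 2.62 for type 2 minus secretory, 1.82 to 1.86 for secretory minus ciliated, 3.42 to 3.55 for ciliated minus neuroendocrine, 0.58 to 0.70 for capillary minus aerocyte, 3.68 to 3.70 for endothelial minus lymphatic, 0.33 to 0.49 for arterial minus venous. The same ranges were 1.94 to 2.06 for alveolar fibroblast minus myofibroblast, 1.01 to 1.02 for alveolar minus adventitial fibroblast, -0.09 to -0.06 for smooth muscle minus pericyte, 0.89 to 0.92 for macrophage minus neutrophil, 11.54 to 11.63 for adult minus embryonic globin, 0.60 to 0.64 for collagen minus elastic fibre. Detected genes ranged from 14671 to 14911 with each pup left out, and were 19231 at TPM 0.1, 10497 at TPM 5, 17158 with posterior mean TPM, 17169 with at least 10 counts in both pups and 14169 with effective length of at least 200. Isoform genes with a leading transcript over 50% numbered 12 with either pup left out and with posterior means. The number of cell type lists with at least 50% of members detected stayed at 26 of 29.

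Pearson r between the pups across genes was 0.992 with a pseudocount of 0.1, 0.993 with all genes above 0 in either pup, 0.993 with FPKM, 0.994 with TMM-scaled CPM and 0.994 with protein-coding genes only. The number of genes that differ between the pups was 799 at 1.5-fold, 46 at 4-fold, 590 with at least 10 counts, 30 with at least 500 counts and 85 with deposited TPM. The pseudocount of 1 accounts for part of the last fall. With it, genes under TPM 1 in both pups, such as Slc7a11 (0.12 and 0.76 TPM), cannot reach 2-fold. How much of the fall this covers was not tested. With the mean in place of the median 10 of 57 lists fell outside the central 95%, and the shift of the red cell list turned from -0.15 to 0.0134. As shares of TPM, mitochondrial genes held 3.15%, protein-coding genes 86.4% and spike-ins 0.00166%. Summed TPM rose by 3.24% to 3.27% when spike-ins and mitochondrial genes were left out of the total. A count was taken as the same within 1.5 times, a level or difference within 1 SD of the pups and a list shift when its call held, while any change of r was taken as moved. Counting each value of a main result under each alternative separately, 79 values stayed the same, 66 moved and 3 reversed, and for the other results 287 values stayed the same, 15 moved, 16 became weaker and 1 reversed. Every alternative fixed in advance was run. Depth limits the reading of counts near the floor of 3.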

Other observations

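The atrial and neutrophil tests below were chosen after the result was seen, and so were the lists used to weigh each pattern, which were drawn up once the differences between the pups were known.

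Further milk protein genes rose with Csn2 in pup 3, and the genes of this paragraph were named after their values were seen. Csn1s2a, a casein gene, had 7 counts in pup 1 and 532 in pup 3, Csn3 had 3 and 299 and Lalba, which encodes alpha-lactalbumin, 6 and 54. Chemokine and cytokine genes rose with Ccl20. Cxcl1 had 50 and 622 counts, Ccl4 27 and 215, Cxcl5 11 and 354 and Il1b 177 and 370.

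Milk and chemokine transcripts in pup 3 may have separate sources. A second list of 9 lactation genes fell at percentile 0 of matched lists (pup 1 over pup 3), which fits milk or mammary RNA in that library, although Xdh, Elf5 and Thrsp were not lower in pup 1. Only 3 of the 9 reached TPM 1 in both pups and 1 passed the size rule, so the median rests on genes of low count. Summed TPM of this list was not higher in pup 3 (33.8 and 32.6 TPM in pups 1 and 3). A list of 16 NF-kappa-B targets also fell at percentile 0, with all 16 higher in pup 3, which fits an inflammatory response. More neutrophils would have lowered the neutrophil list, whose median log2 ratio was -0.0197. Whether milk RNA entered in the pup or from another library was not tested.

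Glucocorticoid-responsive genes were higher in pup 1, and stronger glucocorticoid signalling is a candidate explanation, since a second list of 14 such genes fell at percentile 100 of matched lists. A change of scaling moves every gene alike, so it fixes the lowest median under 3 other scalings (0.39) and cannot set the list apart from matched lists, while length and GC trends left 0.42 once subtracted. A fasting response would have raised fatty acid oxidation genes, which fell at percentile 53.4. Clock genes had a median absolute log2 ratio at percentile 96.8, so a different clock phase stays open. Leaving out any of its 5 highest members brought the median of the first list to 0.11.

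Cardiac muscle transcripts could come from heart tissue carried over at dissection. Myl2, a ventricular gene, reached at most 0.863% of Myl7, and Nppa, an atrial gene, at most 0.859%, both below the limits set for these tests. The Myl2 value argues against ventricular tissue as the main source of Myl7. It cannot exclude a small amount of such tissue, since Myl2 had 44 and 46 counts in pups 1 and 3. The Nppa limit was set after the result was seen, so atrial tissue is not excluded either. The atrial list summed to 427 ± 57.7 TPM, mostly Myl7 and Myl4 (71.3 and 77.8 TPM), with Bmp10 at 0 counts in both pups, and the ventricular list to 34.5 ± 1.76 TPM. Muscle of the pulmonary veins was not tested. The series has 1 group, so no comparison between conditions bears on these explanations.

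A list of 10 sterol synthesis and uptake genes, added after the data were seen, had a median log2 ratio of -0.07, at percentile 6.94 of matched lists.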
